A study of Mus musculus with 8 samples.

How the data were processed

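Total RNA of TC1 mouse embryonic stem cells was sequenced at day 0, before differentiation, and at day 10 of differentiation, with 4 libraries per day and no other group. Per the labels, all cells were wild-type, and RNA was prepared with a total RNA kit that includes ribosomal RNA depletion. The comparison was day 10 against day 0. Each day's libraries carry the replicate numbers 1 to 4, and no label says what a number stands for or whether libraries of a day came from separate cultures. No batch or date is given, so a batch that followed the day cannot be told apart from it.

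The authors deposited 1 table per library with 126126 transcripts, holding per the file headers the transcript length, effective length, estimated count and TPM. Quantification used kallisto, per the submitters' processing notes, which give its version only as 1 and also name DESeq2. The transcript reference, genome build and annotation are not given in the sources used here. The estimated counts deposited by the authors are not scaled. Of all values of a library, zeros included, 40.3 to 46.3% were not whole within 1e-06, since reads that fit several transcripts are shared out between them. The TPM values deposited by the authors are scaled for effective length and sum to 1000000 per library, within rounding. Results of the authors' own DESeq2 analysis were not used here.

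Transcripts were matched to GENCODE M21 by identifier without version, which matched 117992 transcripts (93.6%). Of the matched ones 98.4% had equal length in both sources, and 0.01% carried an equal version. The 8134 transcripts without a match held 1.15 to 1.23% of each library's counts and were left out of the gene tests. M21 supplied gene names, types, chromosomes, lengths and GC content, and no positions are given since the build is unknown. Estimated counts were summed over 32780 genes and rounded, and 45 repeated symbols were made distinct. Between 13044 and 14381 genes per library reached 1 CPM. Kallisto shares reads between paralogues and overlapping transcripts without using any statement on strand, so near-identical family members and antisense genes are uncertain one by one.

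Genes were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood fit), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Changes over 2-fold were tested with glmTreat against a log2 change of 1. SE is the absolute log2 change divided by the square root of the quasi-likelihood F. The common biological coefficient of variation was 12.5%. CPM values are scaled by TMM. For a gene with 0 counts in a group, the fold is a bound against a floor of 3 counts over the group, and for 1 to 3 counts the ratio carries a 95% exact counting interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

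The 37 gene lists, the named-genes rule, the main tests and the alternatives were fixed before the data were examined. Tests, groups and corrections chosen later are named as such where they appear. The lists cover cohesin core subunits and regulators, meiotic cohesin, condensin and SMC5/6, replication, mitosis, CDK inhibitors and D cyclins, pluripotency, formative epiblast, the 2-cell-like state, primitive streak, cardiac transcription factors, sarcomere, and cardiac calcium and ion channel genes. They further cover smooth and skeletal muscle, endothelium, blood, matrix, epicardium, visceral and parietal endoderm, neural, epithelial and trophoblast markers, oxidative phosphorylation, fatty acid and glycolysis genes, and DNA methylation and polycomb genes. The rest are imprinted genes, immediate early genes, p53 targets, Hox genes, protocadherins, histones, ribosomal proteins and mitochondrially encoded genes. Each list and each of 20 chromosomes was tested against all other tested genes with limma 3.58.1 (camera on voom values, preset correlation 0.01, two-sided), with camera at an estimated correlation and fry beside it. Counts of called members are given over all genes tested and adjusted over the list alone. Shares of counts were compared with two-sided exact permutation tests over 70 assignments, for which the smallest p is 0.0286, adjusted over 7 shares. The mitochondrial, histone and most abundant gene shares were planned. Those of ribosomal proteins, Malat1, Grip2 and long non-coding RNAs were not in that plan.

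The named genes are 152, of which 2 are not reported here, 1 of them also among the single libraries that stood apart. The rule took all measured members of the lists on cohesin core subunits and regulators. It took the 6 protein-coding genes with the highest and the 6 with the lowest log2 change among called genes of at least 10 CPM whose groups did not overlap. From each other list it took up to 3 called members with the smallest p in the list's main direction and the 1 with the smallest p in the other direction. Genes outside the rule are named as chosen after their values were seen.

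Alternatives were DESeq2 size factors, upper quartile scaling, no low-count filter, a filter of 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, voom with sample quality weights, the average transcript length as an offset, limma-trend on log2(TPM + 1), protein-coding genes alone, removal of mitochondrial and small RNA genes, the replicate number as a block, and each library left out in turn. A correction that removes each library's loess trend with transcript length and GC content (span 0.5) as an offset was added after the length trend was seen.

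The procedure was tested on simulated data for day 10 against day 0, with 15097 genes of which 200 were changed, 50 at each fold, and 4 libraries per group. It recovered 12% of genes changed 1.25-fold, 50% at 1.5-fold, 80% at 2-fold and 96% at 4-fold, with 2 false calls among 121. Of 20 simulated lists of 25 genes it recovered 5 of 5 shifted 1.5-fold and called 0 others. In both simulations few genes changed and genes varied independently. In the data 12399 genes were called, and list members were correlated, at an estimated 0.79 for cohesin core subunits. The rates of recovery and of false calls therefore do not carry over to the data. With a simulated length trend of 0.5 per doubling and no change, 5323 genes were called without the length correction and 5 with it. Libraries of a day were checked for duplication, and counts of each pair differed by 3.92 to 26.4 times the Poisson variance.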

Results

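The series measured total RNA from TC1 cells, a wild-type mouse embryonic stem cell line, in 2 states. The first was the undifferentiated culture at day 0 and the second the differentiated culture at day 10, with 4 libraries each. Both cultures were dissociated before RNA extraction, per the series description, and the title places the work in a study of cohesin, the ring-shaped complex that holds sister chromatids together and extrudes chromatin loops. Estimated counts totalled 11242568 to 15808039 per library at day 0 and 13525255 to 17843651 at day 10, so depth overlapped between the groups. Log expression of library pairs correlated across genes at r = 0.987 to 0.991 within day 0, 0.979 to 0.989 within day 10 and 0.701 to 0.735 between days, genes not being independent replicates. The biological coefficient of variation was 10.4% at day 0 and 14.4% at day 10. No label says that the 4 libraries of a day came from separate cultures, so p-values measure the spread between these samples, which may be technical. Expression is given as CPM (counts scaled to a library of 1000000), mean ± SD over n = 4 libraries per day. Fold changes are log2 of day 10 over day 0, ± SE, with adjusted p from edgeR's quasi-likelihood test.

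Between day 0 and day 10 all 25 pluripotency genes tested and all 11 meiotic cohesin and axis genes fell, while most tested genes of the cardiac, smooth muscle, endothelial, blood, matrix, epicardial and visceral endoderm lists rose. As sets these lists passed camera at its preset correlation, and 0 of all 37 lists passed with an estimated one (10 before adjustment there, 31 by fry, 24 with DESeq2). Of 15097 genes tested, 12399 changed, 6449 upward and 5950 downward, and 6245 changed by more than 2-fold (3633 up, 2612 down). The steepest rises among protein-coding genes included Col3a1, a fibrillar collagen, from 0.650 ± 0.254 to 2789 ± 618 CPM (log2 12.09 ± 0.29, adjusted p = 1.05e-10). Cd93, a receptor of endothelial and myeloid cells, had 0 counts over the 4 day 0 libraries and 87.9 ± 12.2 CPM at day 10, at least 1550-fold higher. Against a floor of 3 counts over the group, Muc16, a membrane mucin, was at least 1180-fold higher, Plek, a haematopoietic signalling protein, at least 942-fold, and Colec10, a collectin, at least 699-fold. Lum, a matrix proteoglycan, went from 1 count to 13143, a ratio of 11200 with a 95% counting interval of 2010 to 443000.

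The steepest falls were in Hormad1, a meiotic chromosome axis gene, with 82.0 ± 7.51 CPM at day 0 and 0 counts at day 10, at least 1690-fold lower. Fgf4, a growth factor of the epiblast, went from 15872 counts to 3, a day 10 to day 0 ratio of 0.000161 (counting interval 3.33e-05 to 0.000472). Dnmt3l, a cofactor of DNA methylation, kept 2 of 6378 counts (ratio 0.000268, 3.24e-05 to 0.000968) and the zinc finger gene Zfp987 1 of 3763 (ratio 0.000227, 5.74e-06 to 0.00127). Psma8 and Mael, both germ-line genes, had 0 counts at day 10, at least 425-fold and 410-fold lower. The counts of Lum lay in day 0 library 4 alone and those of Fgf4, Dnmt3l and Zfp987 in day 10 library 2, 3 and 1, and without that library the fitted log2 changes, which are no bounds, were 14.58, -15.03, -13.76 and -13.02. These intervals and floors cover counting error only.

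The balance of rises and falls differed between counts and TPM. With limma-trend on the authors' TPM values, which changes unit, length scaling and test together, the median log2 fold change of all tested genes was 0.40 against 0.06 on counts, and 65.8% of called genes were higher against 52%. For changes over 2-fold the share called higher was 74.5% on TPM against 58.2% on counts. With DESeq2 size factors or upper quartile scaling of the counts, 52.6% and 51.6% of called genes were higher. Changes also followed transcript length. The median log2 fold change of protein-coding genes went from -1.42 for those up to 500 nucleotides (105 genes) to 0.93 for those over 6000 (721 genes). Values of named genes and list medians after removal of this trend are given below where they end or make a call, turn a direction or alter a log2 value by over 1.5 times. Counts of called list members are without this removal unless stated.

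**Figure D1:**
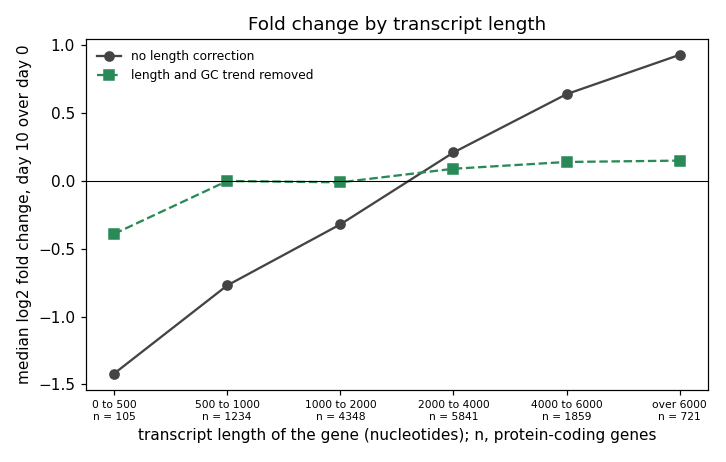
Median log2 fold change (vertical axis) of protein-coding genes in 6 classes of transcript length (horizontal axis, nucleotides), with no correction (circles) and with each library's trend with length and GC content removed (squares). The uncorrected medians rise from -1.42 in the shortest class to 0.93 in the longest, and the corrected ones run from -0.39 to 0.15.

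The first question the title raises is how transcripts of the cohesin complex itself differed. Within the ring, Smc3 and Rad21 were lower at day 10, while both STAG subunits stayed near or above their day 0 level. Smc3 (ENSMUSG00000024974, chromosome 19) fell from 486 ± 50 to 228 ± 20.7 CPM, a log2 change of -1.09 ± 0.08 (adjusted p = 2.08e-08). Rad21 (ENSMUSG00000022314, chromosome 15), the subunit that closes the ring, fell from 391 ± 18.9 to 231 ± 7.15 CPM (log2 -0.76 ± 0.06, adjusted p = 2.05e-08). Smc3 was at -0.69 with the average transcript length as an offset, and on TPM Smc3 was at -0.31 and Rad21 at -0.39, or -0.71 and -0.78 relative to the median of all genes. Stag1 (ENSMUSG00000037286, chromosome 9) rose from 241 ± 9.52 to 305 ± 7.98 CPM (log2 0.34 ± 0.06, adjusted p = 6.15e-05), a call that ended with the length trend removed (log2 0.08, adjusted p = 0.124, the highest of 20 alternatives from 1.52e-09). Stag2 (ENSMUSG00000025862, chromosome X) was at 398 ± 19.8 and 425 ± 15.8 CPM (log2 0.09 ± 0.06, adjusted p = 0.162). Stag1 was at 0.87 on TPM, or 0.47 relative to that median. Stag2 passed the test under 4 of 20 alternatives. Among them were the length trend removed (log2 0.21), the average transcript length as an offset (log2 0.53) and TPM (log2 0.93, or 0.54 relative to the median of all genes).

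Smc1a (ENSMUSG00000041133, chromosome X) fell on counts, from 151 ± 13 to 118 ± 11.5 CPM (log2 -0.35 ± 0.08, adjusted p = 0.00118), and its direction depended on the unit. With the average transcript length as an offset its log2 change was 0.19 (adjusted p = 0.0886), and on TPM it was 0.58 (adjusted p = 0.000461), or 0.18 relative to the median of all genes. Over 20 alternatives its adjusted p was 0.000117 to 0.0886. Of the 5 core subunits tested, 1 rose, 3 fell and 1 did not pass, with equal numbers when adjusted over the list alone, and the list as a set did not differ from other genes (median log2 -0.35 on counts and 0.58 on TPM, adjusted p = 0.434 on counts).

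Cohesin regulators fell as a group on counts. Of 14 measured, 10 fell and 3 rose, with the same numbers adjusted over the list alone (median log2 -0.90, adjusted p = 0.0138, and adjusted p = 0.224 with an estimated correlation). Esco2, the acetyltransferase that establishes cohesion during replication, fell from 304 ± 18.5 to 61.2 ± 12.3 CPM (log2 -2.31 ± 0.13). Espl1, which encodes separase, fell by 2.05 ± 0.08 on the log2 scale, the shugoshins Sgo1 by 1.96 ± 0.10 and Sgo2a by 1.96 ± 0.07, Cdca5, which encodes sororin, by 1.80 ± 0.10, and Pttg1, which encodes securin, by 1.46 ± 0.13. Of these 6 genes Pttg1 moved most with the length trend removed, to a log2 change of -0.43. Adjusted p ran from 5.74e-12 for Sgo2a to 7.67e-08 for Pttg1.

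The release factor Wapl fell from 671 ± 38.9 to 357 ± 15.4 CPM (log2 -0.91 ± 0.06, adjusted p = 5.89e-09, or -1.37 with the length trend removed), and the acetyltransferase Esco1 fell from 88.7 ± 9.87 to 47.9 ± 6.03 CPM (log2 -0.89 ± 0.10). On TPM Wapl was at -0.56, Esco1 at -0.26 and Espl1 at -1.19, or -0.95, -0.66 and -1.59 relative to the median of all genes. Pds5a fell by 0.33 ± 0.06 and Ctcf, the boundary factor at which loop extrusion stops, by 0.49 ± 0.06 on the log2 scale, on counts, whereas on TPM their log2 changes were 0.20 and 0.08, or -0.19 and -0.32 relative to the median of all genes. With the average transcript length as an offset they were at -0.19 and -0.32. The regulators that rose were Hdac8, the SMC3 deacetylase, from 4.23 ± 0.691 to 9.45 ± 1.0 CPM (log2 1.16 ± 0.17), the loader subunit Mau2 and Pds5b. Mau2 rose by 0.72 ± 0.08 on the log2 scale, or 0.40 with the length trend removed, and Pds5b by 0.40 ± 0.06 on counts, whereas with the trend removed it was lower, at -0.18, and on TPM it was at 0.92, or 0.52 relative to the median of all genes. Nipbl, the other loader subunit, was at 500 ± 44.5 and 514 ± 21.2 CPM (log2 0.04 ± 0.07, adjusted p = 0.593). Its direction turned with the length trend removed, at -0.76, and it was at 0.47 on TPM (0.08 relative to the median of all genes), both past the threshold.

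**Figure D2:**
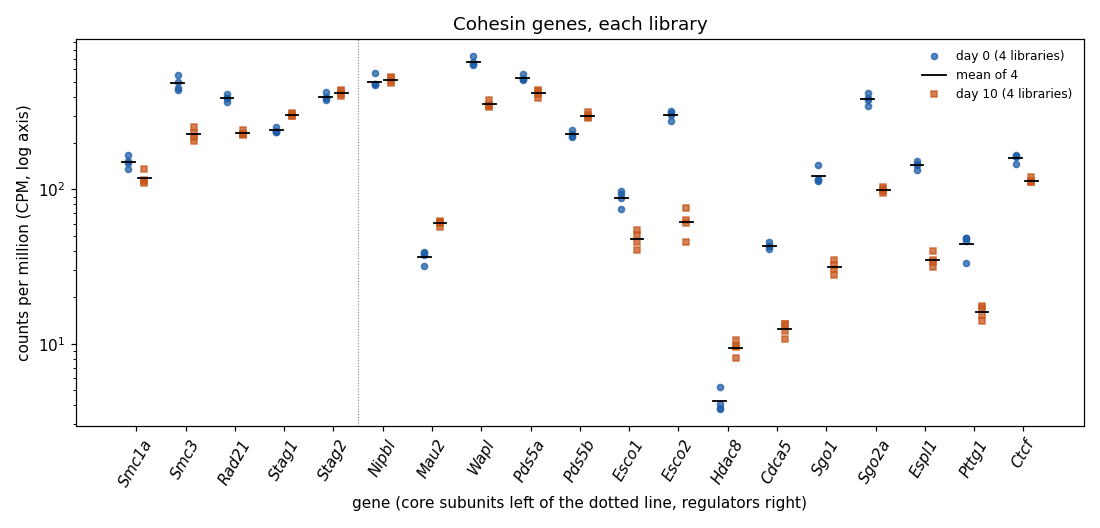
CPM (scaled counts, vertical axis, log scale) of the 19 measured cohesin genes (horizontal axis) in each of the 4 day 0 libraries (circles) and 4 day 10 libraries (squares), with black bars for the mean of 4. Esco2 sits at 304 CPM on average at day 0 and 61.2 at day 10, while Stag2 sits at 398 and 425.

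Meiotic cohesin and axis genes, which the undifferentiated cells transcribed at low to moderate levels, fell throughout. All 11 tested fell, also adjusted over the list alone (median log2 -4.60, adjusted p = 6.63e-05, and adjusted p = 0.164 with an estimated correlation). Stag3, the meiotic STAG subunit, fell from 107 ± 6.02 to 9.67 ± 0.876 CPM (log2 -3.47 ± 0.09) and Smc1b, the meiotic SMC1 paralogue, from 51.3 ± 5.29 to 0.652 ± 0.236 CPM (log2 -6.25 ± 0.18). Condensin and SMC5/6 genes showed smaller changes, with 11 of 15 lower and 4 not passing (10 lower adjusted over the list alone). Their median was -0.56 on the log2 scale (adjusted p = 0.00361, adjusted p = 0.268 with an estimated correlation, and adjusted p = 0.111 on TPM, where the median was -0.05). Ncapg fell by 1.36 ± 0.07, Ncaph2 by 1.18 ± 0.07 and Nsmce4a by 1.37 ± 0.08, the last by 0.69 with the length trend removed.

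Proliferation genes fell together. All 34 DNA replication genes tested fell (median log2 -1.32, adjusted p = 7.05e-11, and adjusted p = 0.164 with an estimated correlation), among them the helicase subunits Mcm2 (log2 -1.64 ± 0.06) and Mcm6 (log2 -1.42 ± 0.06) and the clamp loader Rfc5 (log2 -2.10 ± 0.08). With the length trend removed 31 of the 34 were called lower and 1 higher. All 25 mitosis genes fell (median log2 -1.53, adjusted p = 6.31e-10, and adjusted p = 0.091 with an estimated correlation). Bub1b, a checkpoint kinase, went from 320 ± 15.6 to 91.6 ± 2.40 CPM, Ccnb1 from 345 ± 17.6 to 98.8 ± 5.89 and Tpx2, a spindle assembly factor, from 346 ± 15.3 to 113 ± 3.65. For both lists the numbers adjusted over the list alone were identical. Among CDK inhibitors and D cyclins 6 of 10 rose and 1 fell, as adjusted over the list alone, and the set did not differ from other genes (adjusted p = 0.306). Cdkn2b (log2 4.14 ± 0.25), Cdkn1c (log2 2.68 ± 0.16) and Ccnd2 (log2 1.96 ± 0.15) rose, and Ccnd1 fell (log2 -1.07 ± 0.23). At day 10 Cdkn1c was at 227 CPM in library 2 and 362 to 386 in the others.

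Stem cell identity genes fell, from a summed 5696 ± 218 CPM at day 0 to 421 ± 97.3 at day 10. All 25 pluripotency genes fell, also adjusted over the list alone (median log2 -6.59, adjusted p = 4.96e-09, and adjusted p = 0.164 with an estimated correlation). Pou5f1, which encodes OCT4, fell from 738 ± 64.5 to 2.72 ± 0.713 CPM (log2 -8.06 ± 0.14), Esrrb from 306 ± 18 to 2.71 ± 0.570 CPM (log2 -6.81 ± 0.11) and Dppa5a from 470 ± 53.7 to 0.650 ± 0.207 CPM (log2 -9.51 ± 0.15). Of 14 genes of the formative and primed epiblast 11 fell and 2 rose, also adjusted over the list alone (median log2 -3.12, adjusted p = 0.00128, and adjusted p = 0.207 with an estimated correlation). The Nodal pathway genes Lefty2 (log2 -6.51 ± 0.15), Nodal (log2 -5.45 ± 0.19) and Lefty1 (log2 -4.94 ± 0.18) were among those that fell, and Sall2 rose (log2 1.60 ± 0.11). With the length trend removed Sall2 was at 1.03.

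Transcripts of the 2-cell-like state, a rare state of stem cell cultures, were detected at day 0 only at low level. All 4 members tested fell, also adjusted over the list alone (adjusted p = 0.0123, adjusted p = 0.268 with an estimated correlation, and adjusted p = 0.133 in DESeq2). Zscan4c, Zscan4d and Zscan4e had 107, 127 and 109 counts at day 0 and 0 at day 10, at least 41.6-fold, 49.5-fold and 42.5-fold lower. The fitted median was -8.01 and, with genes at 0 set to their bound, -5.52. These Zscan4 paralogues are near-identical, so the split of reads between them is uncertain. Primitive streak and early mesoderm genes were low on both days, with 2 of 7 higher and 3 lower, as adjusted over the list alone, and no shift as a set (adjusted p = 0.637, median -0.07, or -0.28 with the length trend removed). Mesp2 (log2 -3.08 ± 0.48) and Eomes (log2 -1.49 ± 0.30) fell and Lhx1 rose (log2 3.04 ± 0.48). T, which encodes brachyury, fell by 1.82 ± 0.64 (adjusted p = 0.0214). Its day 10 level rested on library 2, at 2.28 CPM against 0.0730 to 0.392 in the others, and without that library the change was -3.28, whereas the call ended without day 0 library 2, without day 10 library 4 and with no low-count filter (adjusted p = 2.1e-06 to 0.0584 over 20 alternatives).

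Cardiac genes rose. Of 19 cardiac transcription factors tested 18 rose and 1 fell, also adjusted over the list alone (median log2 3.74, adjusted p = 1.53e-05, and adjusted p = 0.164 with an estimated correlation). Tbx20 rose from 3.50 ± 0.383 to 199 ± 30.3 CPM (log2 5.82 ± 0.14), Mef2c from 7.15 ± 0.650 to 95.3 ± 7.08 CPM (log2 3.74 ± 0.10) and Isl1, a factor of the second heart field, from 0.477 ± 0.135 to 36.1 ± 6.21 CPM (log2 6.22 ± 0.21). Tbx3, also active in stem cells, fell (log2 -0.56 ± 0.16, or -0.93 with the length trend removed), a call that ended on TPM. Nkx2-5, a core cardiac factor named here after its values were seen, was too low to test, with 2 counts at day 0 and 56 at day 10.

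Sarcomere genes rose in 26 of 27 cases with 1 lower, also adjusted over the list alone (median log2 4.81, adjusted p = 8.61e-06, and adjusted p = 0.295 with an estimated correlation). Tnnt2, cardiac troponin T, rose from 0.0799 ± 0.0766 to 34.9 ± 8.05 CPM (log2 8.68 ± 0.33), Mybpc3 by 5.33 ± 0.20 and Myom1 by 5.34 ± 0.20 on the log2 scale. Cryab, a small heat shock protein, fell on counts (log2 -0.58 ± 0.15), whereas with the length trend removed its direction turned, at 0.06, and the call ended there and on TPM. Of the calcium handling, ion channel and hormone genes of the heart 16 of 19 rose and 1 fell, also adjusted over the list alone (median log2 4.71, adjusted p = 0.000497, and adjusted p = 0.164 with an estimated correlation). The calcium channel genes Cacna1c (log2 5.02 ± 0.17) and Cacna1h (log2 3.75 ± 0.15) rose, and Kcnj3 fell (log2 -3.79 ± 0.21). The natriuretic peptide genes Nppa (0 and 7 counts at day 0 and day 10) and Nppb (52 and 10 counts), also named after their values were seen, were too low to test.

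Markers of other lineages rose beside the cardiac ones. For smooth muscle 11 of 12 rose (median log2 4.23, adjusted p = 0.000608, and adjusted p = 0.295 with an estimated correlation), including the contractile genes Actg2 (log2 9.04 ± 0.33), Mylk (log2 6.95 ± 0.26) and Synpo2 (log2 4.24 ± 0.15). For fibroblasts and extracellular matrix 19 of 20 rose (median log2 7.71, adjusted p = 1.57e-06, and adjusted p = 0.295 with an estimated correlation). The list's summed level went from 1329 ± 55.8 to 17580 ± 3450 CPM, with Lox (log2 7.79 ± 0.19), Pdgfrb (log2 4.46 ± 0.13) and Pdgfra (log2 2.08 ± 0.06) among the clearest. All 10 epicardial and mesothelial genes rose (median log2 4.06, adjusted p = 0.00118, and adjusted p = 0.323 with an estimated correlation), among them Bnc1 (log2 10.24 ± 0.35), Tcf21 (log2 7.72 ± 0.34) and Aldh1a2 (log2 4.29 ± 0.19). The numbers for these 3 lists were equal when adjusted over the list alone.

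Endothelial and blood genes rose as well. Of 19 endothelial genes 16 rose, also adjusted over the list alone (median log2 2.27, adjusted p = 0.000333, and adjusted p = 0.203 with an estimated correlation). Kdr, the VEGF receptor 2 gene, rose from 3.82 ± 0.738 to 208 ± 29.4 CPM (log2 5.76 ± 0.14), Cdh5 by 4.65 ± 0.12 and Tek by 3.85 ± 0.10 on the log2 scale. All 13 blood genes tested rose, also adjusted over the list alone (median log2 6.96, or 5.98 with genes at 0 set to their bound, adjusted p = 0.000484, and adjusted p = 0.184 with an estimated correlation). Runx1 went from 25.1 ± 2.80 to 154 ± 15.5 CPM (log2 2.61 ± 0.10). Hba-a1, an alpha globin with a near-identical paralogue, went from 1 to 726 counts (ratio 620, counting interval 111 to 24500), and Alas2, of erythroid haem synthesis, from 3 to 502 (interval of the ratio 48.6 to 695). Without day 0 library 2 their fitted log2 changes were 10.38 and 7.86, against 8.73 and 6.96 with it.

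Visceral and definitive endoderm genes rose in 17 of 21 cases, also adjusted over the list alone (median log2 6.52, or 5.98 with genes at 0 set to their bound, adjusted p = 0.0102, and adjusted p = 0.503 with an estimated correlation). Rbp4 rose from 0.732 ± 0.361 to 65.7 ± 20 CPM (log2 6.52 ± 0.37), Hnf4a by 2.68 ± 0.21 and Foxa1 by 5.98 ± 0.57 on the log2 scale, the last by 6.97 without day 0 library 2. The day 10 libraries differed in this list, whose summed level was 1290, 4038, 2863 and 2556 CPM in libraries 1 to 4, against 509 ± 21.4 at day 0. Library 2, the highest, was also the lowest of the 4 for the matrix list, at 13100 CPM against 17620 to 21520, and stood apart on the principal component after the one that separated the days (-39.16 against 3.74 to 19.48). Without it 12492 genes and 26 lists were called.

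Parietal endoderm genes went both ways, with 4 of 12 higher and 6 lower, also adjusted over the list alone, and no shift as a set (adjusted p = 0.876, median -0.11, or -0.355 with the length trend removed). Lamc1 (log2 -0.86 ± 0.13, or -1.67 with the length trend removed), Sox7 (log2 -1.36 ± 0.21) and Lamb1 (log2 -0.59 ± 0.13, a call that ended on TPM) fell, and Plat rose (log2 1.60 ± 0.08). Median, mean and the between-gene test were negative for this list, whereas the rotation test fry was positive, as was the median on TPM. Neural genes rose in 10 of 20 cases and fell in 4, also adjusted over the list alone (adjusted p = 0.612 as a set). Ncam1 (log2 4.22 ± 0.15) and Nes (log2 1.15 ± 0.08, or 0.44 with the length trend removed) rose and Nefl fell (log2 -1.38 ± 0.15).

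Of 16 epithelial genes 7 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.941 as a set), with a negative median (-0.13) and between-gene test but a positive mean (0.91) and fry, and a median that was positive on TPM and with the length trend removed (0.145). Krt7 (log2 4.39 ± 0.23) and Krt18 (log2 1.98 ± 0.15) rose, Trp63 went from 1 to 463 counts (ratio 395, counting interval 70.6 to 15600, fitted log2 8.06, or 9.75 without day 0 library 3), and Epcam fell (log2 -2.25 ± 0.15). Of 4 trophoblast genes tested 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.637 as a set), with Gata3 (log2 3.94 ± 0.33) and Gata2 (log2 1.90 ± 0.26) higher and Tfap2c (log2 -1.04 ± 0.16) lower. Skeletal muscle genes were scarce, with 2 of 6 tested higher and 3 lower, also adjusted over the list alone (adjusted p = 0.612 as a set). Mymx, with 527 counts at day 0 and 0 at day 10, was at least 205-fold lower, Actn3 (log2 -2.96 ± 0.29) and Myh3 (log2 -3.34 ± 0.64, or -3.98 without day 10 library 1) fell, and Tnnt3 went from 2 to 201 counts (ratio 85.8, counting interval 23.5 to 714, fitted log2 6.12, or 8.51 without day 0 library 4).

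**Figure D3:**
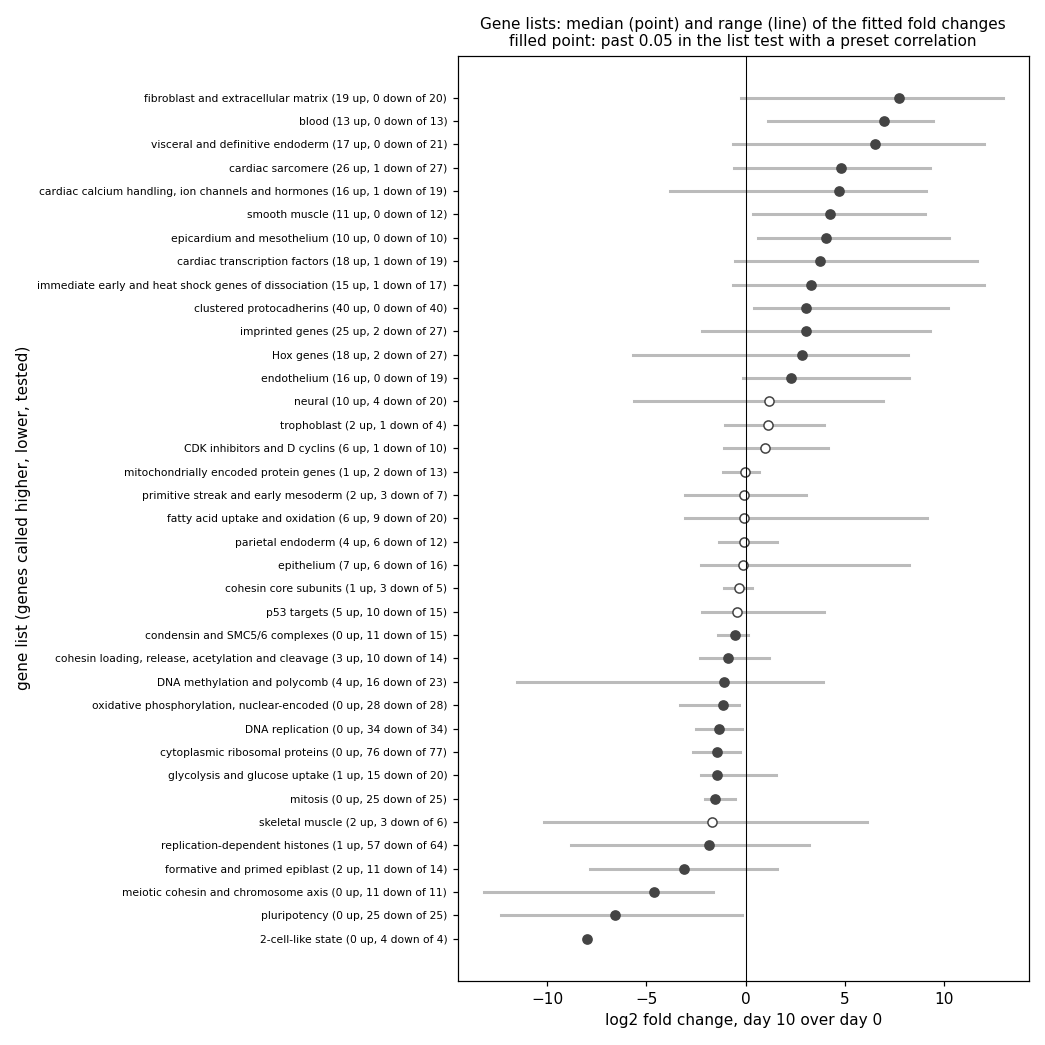
Median (point) and range (line) of fitted log2 fold changes (horizontal axis) for the 37 gene lists (vertical axis, with genes called higher, called lower and tested). Filled points passed the test against other genes with a preset correlation, and none passed with an estimated one. Medians run from -8.01 for the 2-cell-like list, which is -5.52 with genes at 0 set to their bound, to 7.71 for fibroblasts and extracellular matrix.

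Oxidative phosphorylation genes encoded in the nucleus and glycolysis genes fell, and fatty acid genes did not shift as a set. All 28 oxidative phosphorylation genes fell (median log2 -1.14, adjusted p = 1.58e-08, and adjusted p = 0.184 with an estimated correlation). With the length trend removed 24 of the 28 were called lower and 1 higher. Atp5b fell from 1489 ± 87.6 to 505 ± 12.9 CPM (log2 -1.56 ± 0.06), Uqcrc1 fell by 1.68 ± 0.08 and Ndufv2 fell by 1.74 ± 0.08, with -1.11 and -1.07 after removal of the length trend. Of 20 glycolysis and glucose uptake genes 15 fell and 1 rose (median log2 -1.45, adjusted p = 0.000273, and adjusted p = 0.323 with an estimated correlation), with Hk2 (log2 -1.81 ± 0.11), Eno1 (log2 -1.47 ± 0.09) and Gapdh (log2 -1.43 ± 0.09) lower and the insulin-responsive transporter Slc2a4 higher (log2 1.54 ± 0.20). The list's summed level at day 10 was 6333 CPM in library 2 and 4394 to 4556 in the others. Fatty acid genes were mixed, 6 of 20 higher and 9 lower (adjusted p = 0.66 as a set), with a negative median (-0.09) and test but a positive mean (0.70) and a median that was positive on TPM and with the length trend removed (0.11). Acadm (log2 -1.69 ± 0.07), Fabp3 (log2 -3.06 ± 0.20) and Etfb (log2 -1.04 ± 0.11, or -0.35 with the length trend removed) fell and the coactivator Ppargc1a rose (log2 7.16 ± 0.41, or 8.51 without day 0 library 3). Numbers for these 3 lists were equal when adjusted over the list alone.

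Translation and chromatin packaging genes, which have short transcripts, also fell. Of 77 cytoplasmic ribosomal protein genes 76 fell (median log2 -1.43, adjusted p = 2.75e-16, and adjusted p = 0.207 with an estimated correlation). Their share of counts was 4.09 ± 0.465% at day 0 and 1.61 ± 0.0558% at day 10 (exact permutation p = 0.0286, the smallest that 70 assignments allow, 0.05 after adjustment over 7 shares). Rpl4 (log2 -1.52 ± 0.06), Rps12 (log2 -2.48 ± 0.09, or -1.49 with the length trend removed) and Rpl37 (log2 -2.66 ± 0.10, or -1.70) were among them. Of 64 replication-dependent histone genes 57 fell and 1 rose (median log2 -1.85, adjusted p = 1.55e-09, and adjusted p = 0.268 with an estimated correlation), and their share went from 0.490 ± 0.0758% to 0.158 ± 0.0193% (exact permutation p = 0.0286, 0.05 after adjustment). Hist1h1a (log2 -2.13 ± 0.07, or -1.35 with the length trend removed), Hist1h1d (log2 -2.18 ± 0.10) and Hist1h2ak (log2 -2.25 ± 0.11, or -1.43) fell and Hist1h2bq rose (log2 3.21 ± 0.75, or 3.92 without day 0 library 3). Histone paralogues share sequence, so single members are uncertain. Numbers adjusted over the list alone were the same for both lists. The ribosomal protein share was outside the plan, and counting unplanned shares at the same smallest p lowers the adjusted value of the planned histone share. With the length trend removed the medians were -0.59 for ribosomal proteins, -1.10 for histones and -0.71 for oxidative phosphorylation, all still past the test at the preset correlation. Then 60 ribosomal protein genes were called lower and 2 higher, and 54 histone genes lower and 1 higher.

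Mitochondrially encoded genes differed little on counts. Of 13 genes 1 rose and 2 fell, also adjusted over the list alone (median log2 -0.03, adjusted p = 0.613 as a set, and adjusted p = 0.89 with an estimated correlation, of 0.77). With the length trend removed, by contrast, 8 of the 13 were called higher, with a median of 0.78. The set then had an adjusted p of 0.0414 in camera at the preset correlation, the only one used in that fit. mt-Co1 (log2 -0.46 ± 0.08) and mt-Atp6 (log2 -1.15 ± 0.30) fell, both not past the threshold with the length trend removed (-0.04 and -0.16) and mt-Co1 not on TPM (-0.05), and mt-Nd3 rose (log2 0.66 ± 0.18, or 1.85 with the trend removed). Their share of counts was 2.31 ± 0.183% and 1.93 ± 0.269% (exact permutation p = 0.0571, 0.08 after adjustment), whereas their share of TPM differed by 0.396 percentage points upward (exact permutation p = 0.514). The 10 most abundant genes of each library held 5.57 ± 0.774% at day 0 and 5.76 ± 0.378% at day 10 (exact permutation p = 0.743, 0.867 after adjustment), whereas the same share of TPM differed by -2.13 percentage points, day 10 minus day 0 (exact permutation p = 0.0286). Malat1, a nuclear non-coding RNA, held 0.445 ± 0.0618% and 1.30 ± 0.0241% (exact permutation p = 0.0286, 0.05 after adjustment), and all long non-coding RNAs 1.68 ± 0.199% and 3.28 ± 0.0516% (exact permutation p = 0.0286, 0.05 after adjustment). The Malat1 and long non-coding shares were outside the plan.

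Epigenetic regulators and imprinted genes changed in opposite directions. Of 23 DNA methylation and polycomb genes 16 fell and 4 rose, also adjusted over the list alone (median log2 -1.11, adjusted p = 0.00303, and adjusted p = 0.164 with an estimated correlation). Tet1 fell from 1815 ± 139 to 122.3 ± 11.2 CPM (log2 -3.89 ± 0.09) while Tet3 rose from 28.3 ± 1.99 to 256 ± 4.15 CPM (log2 3.17 ± 0.07, or 2.23 with the length trend removed), both dioxygenases of 5-methylcytosine. Mtf2, a polycomb accessory subunit, fell (log2 -1.54 ± 0.06). Of 27 imprinted genes 25 rose and 2 fell, also adjusted over the list alone (median log2 3.02, adjusted p = 7.28e-08, and adjusted p = 0.173 with an estimated correlation), and their summed level went from 3202 ± 182 to 32110 ± 3530 CPM. H19 rose from 28.9 ± 2.75 to 4546 ± 659 CPM (log2 7.30 ± 0.13), Usp29 by 5.29 ± 0.11 and Grb10 by 3.02 ± 0.08 on the log2 scale, and Snrpn fell (log2 -2.04 ± 0.10).

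Immediate early and heat shock genes, which can also respond to dissociation, rose in 15 of 17 cases with 1 lower, also adjusted over the list alone (median log2 3.31, adjusted p = 8.61e-06, and adjusted p = 0.184 with an estimated correlation). Fosb rose from 0.152 ± 0.0558 to 664 ± 61.8 CPM (log2 12 ± 0.15) and Jun from 16.2 ± 2.22 to 544 ± 42.9 CPM (log2 5.06 ± 0.10). Egr2 went from 3 to 3737 counts (ratio 1060, counting interval 364 to 5160, fitted log2 9.86, or 10.73 without day 0 library 4). Hspa1b was lower (log2 -0.64 ± 0.25, adjusted p = 0.0283), a call that ended without day 0 library 1 or 3 or day 10 library 1 or 3, with a replicate block (adjusted p = 0.0561) and on TPM (adjusted p = 0.00524 to 0.371 over 20 alternatives). Of 15 p53 targets 5 rose and 10 fell, also adjusted over the list alone (adjusted p = 0.238 as a set), with Pmaip1 (log2 -2.19 ± 0.10), Bax (log2 -1.85 ± 0.14) and Aen (log2 -1.19 ± 0.10) lower and Plk2 higher (log2 2.18 ± 0.08).

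Clustered families with positional or single-cell identity roles rose. Of 27 Hox genes tested 18 rose and 2 fell, also adjusted over the list alone (median log2 2.84, adjusted p = 0.0114, adjusted p = 0.164 with an estimated correlation, and adjusted p = 0.0789 in DESeq2). Hoxb2 (log2 5.94 ± 0.39), Hoxb3 (log2 5.01 ± 0.20) and Hoxb4 (log2 3.58 ± 0.20) rose, and Hoxb13 went from 113 to 2 counts (ratio 0.0151, counting interval 0.00181 to 0.0559). All 40 clustered protocadherins tested rose, also adjusted over the list alone (median log2 3.04, adjusted p = 1.52e-09, and adjusted p = 0.164 with an estimated correlation), among them Pcdhb19 (log2 8.06 ± 0.25), Pcdhb17 (log2 6.62 ± 0.23) and Pcdhgc3 (log2 2.68 ± 0.08). Transcripts of this family share exons, so reads may be split between members.

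As tested, 26 of 37 lists differed from other genes with limma's camera at a preset correlation, 13 upward and 13 downward. With an estimated correlation 0 passed adjustment while 10 had an unadjusted camera value under 0.05, and camera on DESeq2's statistics called 24. The rotation test fry, which asks only whether a list's genes move on balance one way, called 31. No chromosome shifted as a whole. Over 20 chromosomes limma's camera called 0, with 0 under 0.05 before adjustment and 0 with DESeq2's statistics, and chromosome medians ran from -0.20 on chromosome 17 to 0.39 on chromosome X.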

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

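The tests of ribosomal RNA carry-over for Grip2 and of heat shock genes for handling, and the length and GC correction, were chosen only after the result was seen.

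The excess of day differences over chance was tested with all 35 splits of the 8 libraries into 4 and 4. For genes called, 1 of 35 splits gave as many as the real 12399, the real one itself, with 0 in the highest other, and for changes over 2-fold 1 of 35, with 6245 and 0. Every other split mixed libraries of both days, so the day difference entered the spread within its groups, which lowers the number of calls. The share of 1 in 35 is also the smallest possible. These splits therefore cannot decide on chance for either count, nor on a batch that followed the day. For lists, 7 of 35 splits gave as many as the real 26, up to 27 in the 6 others, each of which kept 3 libraries of a day together. Such splits keep part of the day contrast, and camera sets genes against each other, so this count cannot decide on chance. Splits with 2 libraries of each day per group called 1 to 11 lists. For chromosomes the real split gave 0 with limma's camera (0 before adjustment, 0 with DESeq2), as did the others, so 35 of 35 were as large.

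The log2 fold change of protein-coding genes rose with transcript length, with Spearman's rho of 0.31 across 14108 genes, which are not independent replicates. Neither fragment lengths, as captured by effective lengths, nor the short-gene lists account for the whole trend, since rho was 0.308 with the length offset and 0.295 without members of those lists. Between isoforms of 1 gene the slope was 0.117 per doubling (95% bootstrap interval 0.08 to 0.153, 1076 genes), against 0.681 between genes. Isoforms share exons and kallisto shares reads between them, which can shrink the slope within genes. The comparison therefore cannot decide whether loss of short transcripts, whatever the gene, made a part or the whole of the trend. After removal of length and GC trends the medians were -0.593 for ribosomal proteins, -0.705 for oxidative phosphorylation and -1.099 for histones, each below the 95% range of 10000 matched random lists (from -0.377, -0.46 and -0.302). The random lists drew genes independently, whereas members of these lists were correlated (estimated 0.41, 0.29 and 0.36), which makes that range too narrow. Genes up to 500 nucleotides also kept a median of -0.39 after the removal. The comparison therefore cannot decide whether length and GC content account for the whole fall of these lists. A difference between the days in cell state stays open, as does a library batch that followed the day.

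Immediate early genes had a median log2 change of 3.31 at day 10. A higher share of nuclear or unspliced RNA could raise unstable transcripts, and the retained-intron share of counts was higher at day 10 without overlap (7.65 to 8.30% against 6.45 to 6.87%). Retained-intron transcripts had a median log2 change of 0.31 (interquartile range -0.44 to 1.06, 9979 transcripts), far under the rise of these genes. The shares of the nuclear RNA Malat1 (0.445 and 1.30%) and of long non-coding RNAs (1.68 and 3.28%) were also higher at day 10. A median over retained-intron transcripts does not bound the rise of unstable ones, so whether this made a part or the whole of the cause stays open. A stress response to dissociation or handling could raise heat shock genes with them, but these went both ways, with a median of -0.096 over Hspa1a (1.32), Hspa1b (-0.64), Dnajb1 (0.44) and Hsph1 (-1.05). Members that go both ways decide nothing, so handling and a difference in cell state cannot be told apart for these genes.

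Grip2 took 2.002% of counts in day 0 library 1 against 0.179 to 0.341% in the other day 0 libraries, far from them, and its counts sit in a transcript annotated for nonsense-mediated decay. Ribosomal RNA carry-over might raise genes with ribosomal RNA-like sequence in this library, where the median ratio to the other 3 libraries was 1.123 over Lars2, Cmss1 and Gm26822 against 8.49 for Grip2. The genes most often named for such reads, Gm42418, Gm26917 and AY036118, were not among the matched transcripts, so carry-over stays open. No biological explanation was tested. The 10 most abundant genes of that library, with Grip2 among them, held 6.73% against 5.14 to 5.24% in the other day 0 libraries. Without Grip2 12396 genes were called.

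Single libraries stood apart from the other 3 of their day in 31 of 307 groups tested (16 at day 0, 15 at day 10), where chance gives about 1 in 20, or 15.3. In 7 of them (Lum, Fgf4, Dnmt3l, Zfp987, Tnnt3, Hba-a1 and Trp63) the other 3 libraries had 0 counts, so 1 to 3 counts in a library were enough and the comparison with chance does not hold for these. Day 10 library 2 was far from the others for T (2.28 CPM against 0.0730 to 0.392), Cdkn1c (227.3 against 361.9 to 385.7), Grb10 (1304 against 1470 to 1502), Mcm2 (162.6 against 150.7 to 151.7) and Fgf4 (0.185 against 0). Day 10 library 4 was apart for Smc1a at 135.5 CPM, Rad21 at 241.5, Ctcf at 119.9, Lefty1 at 1.18, Pmaip1 at 8.35 and Pcdhb19 at 43.9. Day 10 library 1 was apart for Rps12 at 40.3 CPM and Zfp987 at 0.0736, and day 10 library 3 for Dnmt3l at 0.146 CPM. Day 0 library 2 was apart for Nipbl at 566.7 CPM, Pds5a at 559.7, Sgo1 at 144.2, Pttg1 at 33.6, Cdkn1c at 46.0, Epcam at 130.6 and Hba-a1 at 0.0697. Day 0 library 1 was apart for Synpo2 at 2.21 CPM, Plat at 23.0 and Plk2 at 41.1. Day 0 library 3 was apart for Gata2 at 1.35 CPM and Trp63 at 0.0842, and day 0 library 4 for Lum at 0.0655 CPM and Tnnt3 at 0.131.

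Among transcripts with no matched gene, data outside the gene tests, 231 of 935 tested were higher at day 10 and 239 lower.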

How the results depend on the processing

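The length and GC correction was chosen only after the result was seen. Over the alternatives, 735 of 739 list values and 3005 of 3033 named-gene values kept their direction and side of the threshold, 3 and 16 were weaker, 0 and 5 stronger, and 1 and 7 reversed. Called genes ranged from 11711 to 14388. With each library left out in turn they were 12187 to 12492, changes over 2-fold 6213 to 6421, lists 26 and chromosomes 0. The difference (percentage points) in the mitochondrially encoded share of counts was then -0.451 to -0.25, in the replication-dependent histone share of counts -0.368 to -0.311 and in the share of the 10 most abundant genes 0.045 to 0.575. With the average length as an offset Smc1a was at 0.188, and on TPM Smc1a was at 0.576, Pds5a at 0.202 and Ctcf at 0.078 (log2). On TPM the share of the 10 most abundant genes differed by -2.129 percentage points, and the list condensin and SMC5/6 complexes lost its call at a median of -0.051 (adjusted p = 0.000227 to 0.111 over alternatives). In DESeq2 the list 2-cell-like state (-7.4) and the list Hox genes (2.806) lost theirs (0.000796 to 0.133 and 0.00128 to 0.0789). With the length and GC trend removed Nipbl was at -0.759, Pds5b at -0.175, Cryab at 0.058 and the mitochondrially encoded list at 0.781 (adjusted p = 0.0414 to 0.949). In that fit 10830 called genes were shared with equal sign and 275 with opposite sign. With an estimated correlation 0 lists passed camera (10 before adjustment, 31 by fry, 24 with DESeq2). Same-numbered libraries of both days deviated together only weakly (r = 0.030 to 0.049 across genes), though each library's r was highest with its own number. No cutoff was set for this, so a factor shared by equal numbers stays open. The main tests did not take the numbers as pairs. With the replicate block 12298 genes, 6231 over 2-fold, 26 lists and 0 chromosomes were called, and the histone share differed by -0.332 (exact sign-flip permutation p = 0.125, the smallest that 4 pairs allow). The cause of these shifts was not tested, apart from the length trend. Depth limits genes with few counts, and those under the low-count filter, such as Nkx2-5 with 2 counts at day 0 and 56 at day 10, were not tested.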

Other observations

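The tests of zinc finger genes and of cohesin against mitosis genes, the gene groups and ratios below and the named genes in them were chosen only after the result was seen.

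Genes of further groups changed between the days. Among piRNA pathway and germ cell genes, 18 of 19 tested were lower at day 10 and 0 higher in edgeR (median log2 -6.56). Of 41 axon guidance ligands and receptors 38 rose and 3 fell (median log2 3.99), with Unc5c up by 10.48, Nrp1 by 8.59 and Slit2 by 6.10 on the log2 scale and Sema5b at -2.38. Of 22 cytosolic and mitochondrial chaperones 20 fell and 1 rose (median log2 -1.37), and of 14 chaperones of the endoplasmic reticulum 9 fell and 2 rose (median log2 -0.56, or -0.32 with the length trend removed). These lists were not tested as sets.

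Ratios within cohesin differed between the days in 4 of 4 libraries each. The log2 ratio of Wapl to Nipbl went from 0.43 ± 0.06 to -0.53 ± 0.07 (SD), a difference of -0.955, or -0.615 with the length trend removed. That of Esco2 to Esco1 differed by -1.44, or -1.14 with the trend removed, and that of Pds5b to Pds5a by 0.735, or 0.24. The ratio of Stag1 to Stag2 differed by 0.25 on counts but by -0.13 with the length trend removed and -0.05 with the length offset, so its direction depends on the correction. The ratios were picked after the changes of their members were seen, so no p is given for them. Within Stag1 the share of transcript ENSMUST00000041418 was 7.08 ± 1.91% at day 0 and 34.1 ± 1.87% at day 10, and that of ENSMUST00000129269 36.3 ± 9.02% and 3.42 ± 2.20% (exact permutation p = 0.0286, 0.0615 after adjustment over 43 transcripts, so neither passed).

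Part of the zinc finger genes on chromosome 4 may form a group that fell beyond other zinc finger genes. Without Zfp987, which prompted the test, 18 of 26 tested there (69.2%) were called lower and 5 higher (median log2 -2.96). On other chromosomes 43.5% of 324 were called lower and 110 genes higher (median log2 -0.16). The one-sided permutation p for the difference in the share called lower was 0.00979 over 100000 draws. Changes on chromosome 4 were uneven, with Zfp600 at -10.01 and Zfp978 at -9.64 on the log2 scale, whereas Zfp618 rose by 5.05 and Zfp362 by 3.81. The summed level of the 26 genes was 2745 ± 107 CPM at day 0 and 1238 ± 39.3 at day 10. Several share much sequence, so single members are uncertain. The permutation treats genes as independent, so its p can overstate the evidence. A hypothesis found and tested on the same data remains one.

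The fall of cohesin regulators with a role in mitosis may follow that of mitosis genes. The 6 mitotic regulators had a median log2 change of -1.96 and the 8 others -0.15, a difference of -1.81, beside -1.53 for the mitosis list. The groups were drawn after the changes were seen, and the 6 are the lowest of the 14, so no p is given. With the length trend removed the values were -2.22, -0.46 and -1.46, so the mitotic regulators then lay further below the mitosis list, although Pttg1 (-0.43) then fell less than Wapl (-1.37) and Esco1 (-1.14). Whether they fell with it or beyond it stays open.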
